A study of Homo sapiens with 3 samples.

How the data were processed

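Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map BRG1, the ATPase encoded by SMARCA4 in the SWI/SNF chromatin remodelling complex, in wild-type 12Z cells, an established line of human endometriotic epithelial cells. The labels name 2 BRG1 libraries (replicates 1 and 2) and 1 input library of chromatin that was not immunoprecipitated. Nothing in the labels says whether the replicates came from separate cultures, so agreement between them may be technical. Per the labels' protocols, cells were fixed with 1% formaldehyde and chromatin was cut with micrococcal nuclease and briefly sonicated. No separate list for the input was used here.

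Per the submitters' processing notes, the tools were cutadapt, Trim Galore, Bowtie2, SAMtools, Picard, MACS2 and bedtools, and the genome build was GRCh38.p12. Their versions and settings are not given in the sources used here. The deposited data are 3 lists of broad peaks, 1 per replicate and 1 series-wide overlap list. The authors' file gives for each peak a fold enrichment, which is a ratio of signal to background, and the −log10 of its p-value and q-value. The deposited score column held 10 times the −log10 q, cut to a whole number, in all but 3 of 33899 peaks, and was not used. These values are the authors' and served to describe, rank and filter peaks within their own list. In the closing section, the fold and p-value of each shared peak also served to infer the background they imply, taking the fold as a ratio of pileups with 1 added to both and the p-value as Poisson. This treats each peak as a single position, whatever its width. Read counts are not part of the lists, so the depth of each library is unknown and no interval here includes read sampling. The peak names of the overlap list run to 42427, beyond both replicate lists, so it came from a further peak call. All 6343 of its peaks overlapped a peak of each replicate by at least 50% of one of the peaks. Whether that call used pooled reads is not given in the sources used here. These peaks are called shared peaks.

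Analyses were run in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, on chromosomes 1 to 22 and X. Coordinates are those of the authors' files, counted from 1. A table of human genes of assembly GRCh38.p14 gave gene names and neighbourhoods, and none of its coordinates are printed. It holds neither strand nor sequence, so parts of the design fixed before the data were examined were replaced. Promoters were replaced by 3 kb either side of both ends of each protein-coding gene, called gene ends, which include the 3' end. The domain of a transcription start was replaced by the domain of a gene, the positions nearer to its body than to any other protein-coding gene, up to 100 kb away. The planned motif tests, CpG strata, exon and intron classes and the window of 1 kb upstream of a start were not run. Random placements could not avoid assembly gaps.

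A replicate peak was found in the other replicate when a peak there overlapped it by 1 bp or more. Shares carry Wilson 95% intervals, which treat peaks as independent. Overlap was set against 1000 random placements of the other list on the same chromosomes, with a one-sided permutation p whose smallest value is 0.001. Gene-end shares used 1000 placements and a two-sided permutation p, with a smallest value of 0.002. Shares were compared with Fisher's exact test, two-sided. For each of 22 gene lists, written before the data were examined, the number of members with a shared peak was tested two-sided against an exact distribution given 10 strata of domain length (or of gene-end window length), with Benjamini-Hochberg adjustment over the lists and a threshold of 0.05. All 496 list entries matched the gene table, and 19974 genes formed the background. Neighbouring genes are not independent, which the test does not take into account. Shared peaks within 10 kb of each other were joined into clusters.

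The methods were tested on simulated data. With no effect, 500 random lists of 24 genes drawn evenly from 19974 genes gave an unadjusted p below the threshold in 3.0% of cases, and lists drawn in proportion to domain length in 6.8%, against 3.6% with 20 strata. The 10 strata therefore leave some effect of length for lists of long genes. A simulated 4-fold rate was detected in 93.2% of evenly drawn lists and a 2-fold rate in 28.6%. Randomly placed peaks gave a gene-end p below the threshold in 2.5% of 40 simulations.

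Genes were named by a rule fixed before the data were examined. It takes SMARCA4 and SWI/SNF members with a gene-end peak, the nearest gene of the 12 gene-end and 12 distal shared peaks with the highest mean fold percentile over both replicates, the nearest gene of the 10 clusters with the most peaks, up to 4 members per list, and the markers CDH1, EPCAM, ESR1, PGR, VIM, FN1 and ZEB1. Genes named outside the rule are said to be so. Some genes that the rule selects are not reported here. Gene-poor stretches were defined after the data were seen, as positions with at most 4 named protein-coding genes within 2 Mb on a 10 kb grid. Alternatives were other overlap rules, a stricter −log10 q of 5 or more in both replicates, other windows and distances, each replicate alone, and, chosen after seeing the data, other placements and strata and the peaks outside gene-poor stretches. Strata of chromosome and domain length had coarser length classes within each chromosome than the 10 strata of the main test.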

Results

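BRG1 binding was mapped in wild-type 12Z endometriotic epithelial cells in 2 ChIP libraries, with 1 input library. The peak list of replicate 1 held 17399 peaks and that of replicate 2 held 10157. The overlap list held 6343 shared peaks, of which 6293 lay on chromosomes 1 to 22 and X. Peaks were weakly enriched, with a median fold over background of 3.53 in replicate 1, 3.71 in replicate 2 and 3.33 among shared peaks. A −log10 q of 5 or more was reached by 558 peaks of replicate 1 and 538 of replicate 2. Without a second condition, the design allows a comparison between replicates and a description of where the shared peaks lie.

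Of the replicate 1 peaks, 36.6% (6345 of 17323; 95% Wilson interval 35.9 to 37.3%) were found in replicate 2. Of the replicate 2 peaks, 63.9% (6445 of 10082; interval 63.0 to 64.9%) were found in replicate 1. Random placement gave 0.474% and 0.818%, so both shares exceeded chance (one-sided permutation p = 0.001 for each, the smallest that 1000 placements can give). Placement within 500 kb of each peak, chosen after seeing the data, raised the chance values to 3.58% and 6.10%. When 50% of both peaks had to overlap, the shares were 18.6% and 32.0%.

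Replicate peaks of the highest fold quintile were found in the other library more often than those of the lowest. In replicate 2 the share was 81.7% in the highest and 60.2% in the lowest quintile (Fisher's exact test, p = 7.39e-52). In replicate 1 it was 52.4% against 47.2% (Fisher's exact test, p = 1.89e-05), and the share was lowest, 20.4%, in the second quintile. Outside gene-poor stretches the difference widened to 28.5 percentage points in replicate 1 and 32.9 in replicate 2. With 50% of both peaks required, the highest quintile lay below the lowest, by −3.77 points in replicate 1 (Fisher's exact test, p = 0.000548) and −2.26 in replicate 2 (p = 0.146). Ranked by −log10 p in place of fold, the differences were 49.1 and 37.2 points.

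**Figure D1:**
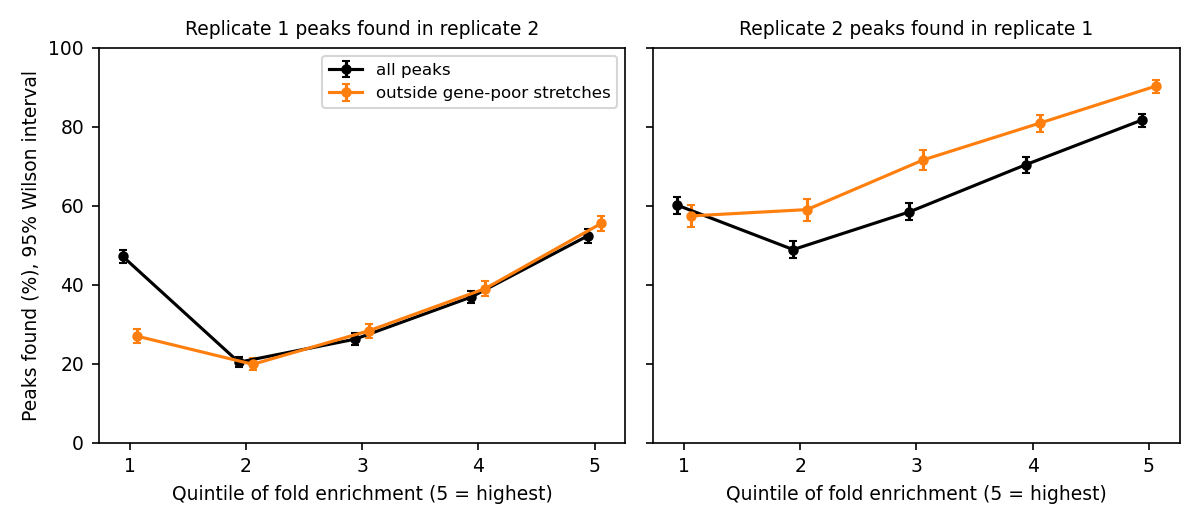
Share of peaks of each replicate found in the other (percent, with 95% Wilson intervals) by quintile of fold enrichment, for all peaks and for those outside gene-poor stretches. The lowest quintile of replicate 1 reached 47.2% over all peaks and 27.0% outside gene-poor stretches.

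Shared peaks were unevenly spread. Gene-poor stretches made up 11.9% of the length and held 2101 of the 6293 shared peaks (33.4%), or 5.82 peaks per Mb against 1.57 elsewhere. The first such stretches of chromosomes 13, 14, 15, 21 and 22 held 1323 of the shared peaks. Each starts at position 1, on the short arm. Of the other stretches of 1 Mb or more, the densest lay on chromosomes 19, 20, 5 and 10. These held 55.2, 41.8, 39.2 and 31.1 shared peaks per Mb and, by their positions, lie near centromeres. The peak lists are labelled as filtered, but the sources used here do not say whether regions of this kind were meant to be removed. Outside gene-poor stretches, shared peaks ranged from 0.078 per Mb on chromosome X to 3.26 on chromosome 20 and 3.53 on chromosome 15. Joining shared peaks within 10 kb gave 151 clusters of 5 or more, of which 127 lay in gene-poor stretches. The cluster with the most peaks, 31, spanned 41843500 to 41915548 on chromosome 10, over 100 kb from its nearest gene ZNF33B. It lay outside the gene-poor stretches as defined. Next came 28 peaks at 17401542 to 17540763 on chromosome 14 (nearest gene OR11H12), in a gene-poor stretch. Another 27 lay at 143184630 to 143275834 on chromosome 1 (nearest gene H3-7), outside such stretches. The other clusters among the top 10 had TUBA3C, POTED, TPTE, CWH43 and OR11H1 as nearest genes. Of these, only the CWH43 cluster lay outside gene-poor stretches. Values for peaks outside gene-poor stretches therefore still include dense clusters, among them 15 peaks at 20238658 to 20333204 on chromosome 15. Each replicate alone gave more clusters, 368 in replicate 1 and 269 in replicate 2, and joining within 5 kb gave 96.

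**Figure D2:**
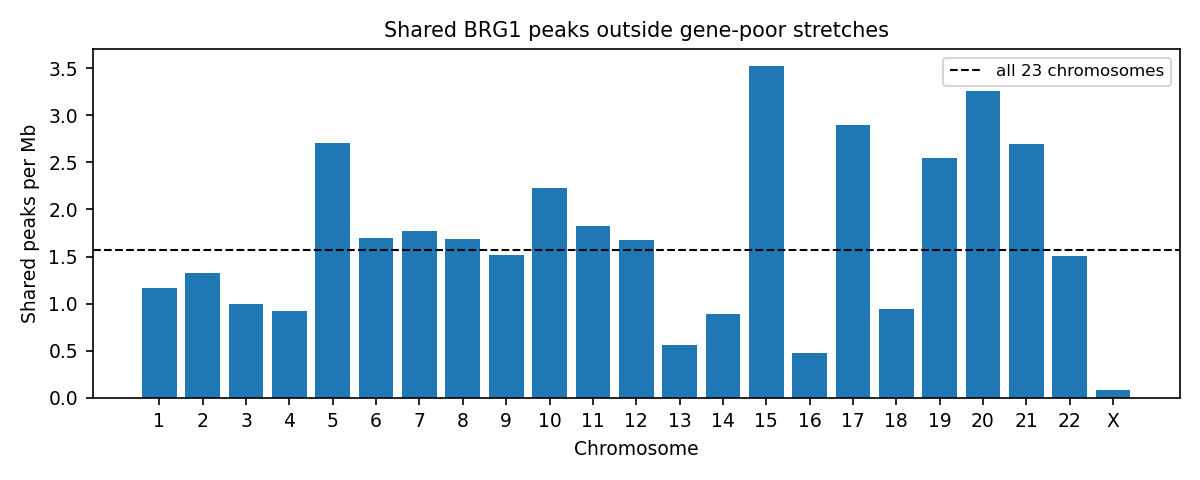
Shared peaks per Mb (bars) on chromosomes 1 to 22 and X outside gene-poor stretches, with the value over all 23 chromosomes as a dashed line at 1.57. Chromosome 15 stood highest at 3.53 and chromosome X lowest at 0.078.

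Within 3 kb of a gene end lay 6.83% of shared peaks (430 of 6293; 95% Wilson interval 6.24 to 7.48%), below the 8.23% of random placement over the chromosome (ratio 0.83, two-sided permutation p = 0.002, the smallest possible). The direction depended on the reference. The ratio was 1.16 (permutation p = 0.004) for placement within 500 kb of each peak and 1.22 (permutation p = 0.002) for the 4192 shared peaks outside gene-poor stretches, of which 10.1% lay at gene ends. That 1.22 came from placement over the whole chromosome, gene-poor stretches included. Placed only outside the stretches, the same peaks gave 1.11 (permutation p = 0.034), with 9.12% at gene ends by random placement. The 242 shared peaks with a −log10 q of 5 or more in both replicates gave 0.15 (permutation p = 0.002). Of these, 45.5% lay in gene-poor stretches, against 33.4% of all shared peaks. Only placement over the chromosome was run for them, so 0.15 does not separate gene ends from gene-poor stretches. Replicate 1 alone gave 1.12 and windows of 1 kb gave 0.98 (permutation p = 0.745). No general preference for or against gene ends can be stated from these values. Among shared peaks 48.5% had no protein-coding gene within 100 kb, and 24.4% of those outside gene-poor stretches.

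The shared gene-end peaks of highest fold rank included 1 within TNFRSF12A, the receptor of the cytokine TWEAK (chromosome 16, 3020793 to 3023060, fold 3.94). Others lay beside TINAGL1 and within DHRS9 and SNAP25. NPTN, TRIM56, UPP1, PEAR1, CARD19, MYEOV and CD151 were nearest to further peaks among the top 12. Away from gene ends, the top peak lay within 100 kb of CEP126 (chromosome 11, 102011037 to 102011621, fold 5.41). It was followed by peaks nearest S1PR1, a sphingosine-1-phosphate receptor, STX16, CCDC85A, DENND5B, SEMA5A and CGNL1. A peak within COL12A1, a collagen gene, lay at 75195967 to 75197023 on chromosome 6 (fold 4.73). PDE4D, CXCL12, MB and OR11H1 were nearest to the remaining top distal peaks, the last in a gene-poor stretch.

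Peaks found in both replicates lay at gene ends less often than peaks of replicate 1 alone, 5.96% against 9.58% (odds ratio 0.60, Fisher's exact test, p = 1.69e-17). For replicate 2 the shares were 5.83% and 5.94% (odds ratio 0.98, Fisher's exact test, p = 0.826). Outside gene-poor stretches the odds ratio of replicate 2 was 0.66 (Fisher's exact test, p = 1.19e-05). It was 0.73 both with windows of 1 kb and with 50% of both peaks required.

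Genes of the YAP/TEAD, collagen and matrix, and integrin and focal adhesion lists had shared peaks in their domains more often than their domain lengths predict. Of 19974 genes, 1910 (9.56%) had a shared peak in their domain, and 10 of the 22 lists were called, all 10 higher. The YAP/TEAD list, of genes in or downstream of the Hippo pathway, had 22 of 29 members bound against 4.71 expected (exact stratified test, adjusted p = 1.57e-12). Examples at gene ends were CCN2, a matricellular growth factor gene (chromosome 6, 131951270 to 131952274, fold 3.68), GADD45A, ASAP1 with 8 shared peaks and RBMS3 with 6. Collagens and matrix genes had 14 of 22 bound against 3.87 expected (exact adjusted p = 7.56e-06), among them COL12A1, COL1A2, DCN and LAMA5. Integrins and focal adhesion genes had 13 of 24 against 3.75 (exact adjusted p = 2.37e-05), with ITGB1 (fold 4.90), ITGB6, LPP and PARVA as examples.

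Inflammatory and NF-kB genes had 11 of 25 bound against 2.28 expected (exact adjusted p = 1.69e-05). The cytokine gene IL6 had a peak at 22731044 to 22731600 on chromosome 7 (fold 4.01), and CCL2 and CSF1 also had gene-end peaks. Mesenchymal genes had 11 of 26 against 3.45 (exact adjusted p = 0.000433), including TNC and ZEB2. Epithelial keratins and identity genes had 6 of 20 against 1.44 (exact adjusted p = 0.00513), including KRT7, KRT8, KRT18 and KRT80. Each of these keratin genes had a peak between 52191946 and 52972250 on chromosome 12. Much of this call thus came from a single region whose genes the test counts as independent. Stromal fibroblast and decidual markers, listed as markers of another cell type, had 8 of 18 against 3.02 (exact adjusted p = 0.0132), with NR2F2, THY1 and ALDH1A2 among them. Without the genes that other lists also hold, 3 of 10 were bound against 1.88 (exact adjusted p = 0.589), and the call was also lost with distal peaks (exact adjusted p = 0.281) and within 1 Mb (exact adjusted p = 0.0899). The TGF-beta list had 8 of 22 against 3.40 (exact adjusted p = 0.0307), with 13 shared peaks nearest SMAD3 and 8 nearest SMURF2. That call was lost within 1 Mb (exact adjusted p = 0.0533) and without genes of other lists (exact adjusted p = 0.0660). Desmosome and hemidesmosome genes had 6 of 20 against 2.38 and endometrial epithelial factors 7 of 20 against 3.08 (exact adjusted p = 0.0454 for both). CD151, PKP2 and DST belonged to the former and LIF, LIFR and HOXA11 to the latter.

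The other 12 lists were not called. SWI/SNF subunits had 5 of 28 bound against 3.10 expected (exact adjusted p = 0.338). SMARCA4 itself had no shared peak, and DPF3 was the only member with one at a gene end. Adherens junction genes had 7 of 20 (3.55 expected, exact adjusted p = 0.123), but were called with replicate 2 alone (9 of 20, exact adjusted p = 0.0427) and with replicate 1 alone (13 of 20, exact adjusted p = 0.0125). Tight junction and polarity genes had 5 of 24 (2.58 expected), PI3K and receptor tyrosine kinases 7 of 22 (4.12), AP-1 factors 2 of 14 (0.93) and p53 targets 2 of 20 (1.41). Cell cycle genes had 2 of 24 (1.77) and ribosomal protein genes 1 of 28 (0.83). Endothelial markers had 1 of 18 (2.58), immune cell markers 1 of 23 (1.43), neuronal genes 3 of 25 (4.31) and hepatocyte genes 1 of 24 (1.92). Of the marker genes, FN1 had 2 shared peaks, while CDH1, EPCAM, ESR1, PGR, VIM and ZEB1 had none in their domains.

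Where both replicate peaks had to reach a −log10 q of 5, 242 shared peaks remained, they reached the domains of 24 genes, and none of the 22 lists was called (exact stratified test, smallest adjusted p = 0.591; 0 lists at an unadjusted p below 0.05). With at most 0.0656 bound genes expected per list, that setting could hardly call a list. It does show that nearly all bound members behind the calls rested on peaks below that q in at least 1 replicate. Bound YAP/TEAD genes fell from 22 to 0 and integrin genes from 13 to 0, while 1 collagen gene and 1 TGF-beta gene remained. Over all genes the number bound fell from 1910 to 24. Of the 242 peaks, 45.5% lay in gene-poor stretches. Whether the stronger peaks by themselves favour these lists cannot be told. The desmosome and endometrial calls were also lost with strata of chromosome and domain length (exact adjusted p = 0.0609 and 0.0558). Their ratios of bound to expected genes changed little there, from 2.52 and 2.27 to 2.33 and 2.16. Both calls were further lost with replicate 2 alone (exact adjusted p = 0.0880 and 0.111) and with distal peaks (exact adjusted p = 0.111 and 0.281). The desmosome call was lost within 1 Mb as well (exact adjusted p = 0.0787). Without genes of other lists its counts stayed at 6 of 20 against 2.38. Only the adjustment over the changed lists moved it past the threshold there (exact adjusted p = 0.0568). The 6 other lists, of YAP/TEAD, collagen and matrix, integrin, inflammatory, mesenchymal and keratin genes, were called in every setting run except the stricter q. None of these settings removed the dependence between neighbouring keratin genes.

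**Figure D3:**
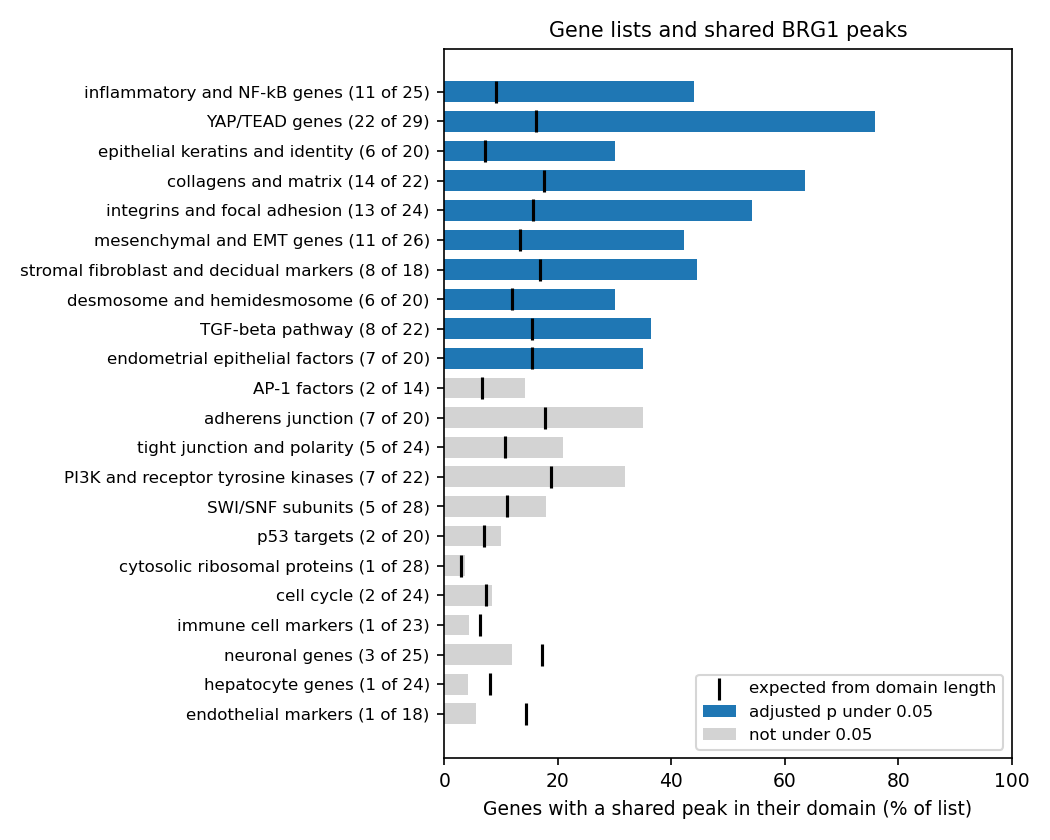
Share of each gene list with a shared BRG1 peak in its domain (bars, percent of members) and the share expected from domain length (vertical marks), with the counts beside each name. Blue lists passed the threshold of 0.05 on the adjusted p, led in adjusted p by YAP/TEAD genes with 22 of 29 bound against 4.71 expected.

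At gene ends 448 genes (2.24%) had a shared peak, and 5 of the 22 lists were called, all 5 higher. They were mesenchymal genes (5 of 26 bound, 0.57 expected, exact adjusted p = 0.00448), YAP/TEAD genes (5 of 29, 0.65 expected, exact adjusted p = 0.00448), stromal markers (4 of 18, 0.41 expected, exact adjusted p = 0.00448), endometrial factors (4 of 20, 0.44 expected, exact adjusted p = 0.00465) and desmosome genes (3 of 20, 0.46 expected, exact adjusted p = 0.0453). With windows of 1 kb, 2 of these 5 stayed called, the mesenchymal and YAP/TEAD lists. The desmosome, endometrial and stromal calls ended (exact adjusted p = 0.122, 0.412 and 0.122), and the inflammatory list was called instead (exact adjusted p = 0.0282). CCN2 counted in both the mesenchymal and the YAP/TEAD call. Lists without genes of other lists were not tested at gene ends. Of the 4 endometrial genes, HOXA11 and HOXA9 had peaks of low fold rank, with mean percentiles of 15.9 and 15.7. With replicate 2 alone the desmosome call ended (exact adjusted p = 0.0682). Replicate 1 alone gave 10 called lists, adherens junction genes among them (5 of 20, exact adjusted p = 0.0335), and the stricter q gave 0, where the 242 peaks reached the ends of 3 genes (exact stratified test, 0 lists at an unadjusted p below 0.05).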

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

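On chromosome Y, which entered the replicate overlap only as an alternative setting, the overlap list held 50 shared peaks, of which 18 lay in gene-poor stretches. They stood out because they lie outside the chromosomes of the main comparisons. They cannot be read as binding on chromosome Y, since the lists do not show whether their reads came from that chromosome. No explanation was tested for them.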

How the results depend on the processing

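Settings on gene-poor stretches, placement within compartments or 500 kb, chromosome strata, 20 strata and genes of 1 list were chosen after seeing the data. Replicate overlap exceeded random placement under all 8 alternatives. Requiring 50% of both peaks turned the quintile differences to −3.77 and −2.26 points (Fisher's exact test, p = 0.000548 and 0.146), while ranking by −log10 p widened them from 5.15 and 21.5 to 49.1 and 37.2. The gene-end ratio of 0.83 became 0.98 with 1 kb windows and 0.15 with the stricter q. Of the peaks left by the stricter q, 45.5% lay in gene-poor stretches. The ratio turned to 1.09 within compartments (permutation p = 0.076) and 1.16 within 500 kb. For peaks outside gene-poor stretches it was 1.22 with placement over the chromosome. With placement also kept outside the stretches it was 1.11 (permutation p = 0.034). The lists without replicate 1 or without replicate 2 gave 0.77 to 1.12. The odds ratio for replicate 2 of 0.98 passed the threshold at 0.73 with 1 kb windows, 0.73 with 50% of both peaks and 0.66 outside gene-poor stretches. The cause of these changes was not tested.

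Lists called at gene ends numbered 5, against 3 with 1 kb windows, 0 with the stricter q, and 5 to 10 without replicate 1 or without replicate 2. Lists called on domains numbered 10, against 0 with the stricter q and 9 to 11 without replicate 1 or without replicate 2. The stricter q left 242 shared peaks, with at most 0.0656 bound genes expected per list, so 0 genes were bound in all 22 lists at gene ends and in 20 on domains, below expectation by construction; for 17 and 16 of these the direction turned from the main result. Of the 10 lists called on domains, 10 remained called within 50 kb, with 20 strata and outside gene-poor stretches, 8 with chromosome strata, and 7 within 1 Mb, with distal peaks and without genes of 2 or more lists. The lists lost were desmosome, endometrial, stromal and TGF-beta genes. Without genes of 2 or more lists, the desmosome list kept all its members and lost its call only through the adjustment over the lists. Uncalled lists also changed side of expectation: adherens junction genes at 0 with 1 kb windows, cell cycle genes at 1 with distal peaks and 2 with chromosome strata, and, without replicate 1 or without replicate 2, tight junction genes at 1 to 2, AP-1 and neuronal genes at 1 and immune markers at 0 to 2 at gene ends, and endothelial markers at 1 to 8 and neuronal genes at 4 to 10 on domains.

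Clusters of 5 or more numbered 151, against 96 joined within 5 kb, 24 outside gene-poor stretches and 269 to 368 without replicate 1 or without replicate 2. Of the other values, 281 for single lists and 39 for main results kept direction and side of the threshold, 19 list values fell short of it and 9 passed it. No paired analysis was possible because both ChIP replicates belong to 1 group. Motif, CpG and upstream-window alternatives were not run. Depth is unknown, so what it limits could not be measured.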

Other observations

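The tests in this part were all chosen after the results were seen. Protein-coding genes were grouped by the letters that begin their symbols, giving 147 families of 15 or more genes, and each was tested on domains as the lists were, with adjustment over the families. Semaphorin genes, which encode guidance signals, had 9 of 20 members bound against 2.98 expected (exact stratified test, adjusted p = 0.0355, and 0.0218 with chromosome strata), among them SEMA5A and, named outside the rule after their values were seen, SEMA3A, SEMA3C, SEMA3D and SEMA3E. Genes named ZNF, mostly zinc finger proteins, had 20 of 517 bound against 40.4 expected (exact adjusted p = 0.0285, and 0.00799 with chromosome strata). Keratin genes had 7 of 55 against 1.55 (exact adjusted p = 0.0378), but not with chromosome strata (exact adjusted p = 0.224). Genes named OR, mostly olfactory receptors, had 6 of 392 bound against 16.1 expected. This passed the threshold only with chromosome strata, which have coarser length classes (exact adjusted p = 0.0211, against 0.196 without them). Several of these genes are neighbours and can share peaks, so the p-values are too small by an unknown amount.

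Counts of shared peaks per domain are not adjusted for domain length. The highest were 30 for TPTE, 28 for LOC124903442 and 21 for CWH43, in domains of 284, 236 and 215 kb; LOC124903442 is also outside the naming rule. Outside the naming rule, and chosen after their values were seen, KCNMA1 had 12 shared peaks in a domain of 944 kb, CAST 12 in 764 kb and THSD4 11 in 722 kb. TRIO (468 kb), ARHGAP26 (519 kb), TENM2 (1399 kb), ATXN1 (564 kb) and EXT1 (428 kb) each had 10. These are outside the rule as well, as are YAP1, which had 5 shared peaks, and TEAD1, which had 3.

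Shared peaks crowded in some gene-poor stretches. Gene-poor sequence in general is argued against, since the median of 70 stretches of 1 Mb or more held 0.107 shared peaks per Mb, 0.068 times the 1.57 found elsewhere, and 14 stretches held 96.5% of the peaks in question. A candidate explanation is reads piled up at repeated sequence. The background that each peak's fold and p-value imply had a median 1.82 times as high in gene-poor stretches as elsewhere (95% bootstrap interval 1.77 to 1.87). The bootstrap treated peaks as independent, although 14 stretches held 96.5% of the peaks in gene-poor stretches. Its interval is therefore too narrow by an unknown amount. The implied background is computed from the fold, whose median was lower in gene-poor stretches (3.03 against 3.45), so it is not a separate measurement of background. It also treats each peak as a single position, although shared peaks were up to 31677 bp wide, so it may differ from the real background. Real binding in these regions stays open, because neither the input reads nor sequence was used here, and no biological explanation was tested.

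Shared peaks outside gene-poor stretches ranged from 0.078 per Mb on chromosome X to 3.53 on chromosome 15. A higher background or copy number of some chromosomes may contribute, since density rose with the median implied background over 23 chromosomes (Spearman's rho = 0.866, permutation p = 1e-05, the smallest possible, adjusted p = 2e-05; Pearson's r = 0.63, permutation p = 0.00072, adjusted p = 0.00144; r = 0.65 without the 2 chromosomes farthest from the median). Gene density stays open, with a weaker relation that missed the threshold (rho = 0.36, permutation p = 0.0919, adjusted p = 0.0919; r = 0.32, permutation p = 0.136, adjusted p = 0.136; r = 0.13 without 2 chromosomes). The implied background ranged only from 4.60 on chromosome X to 6.67 on chromosome 19. Chromosome 13, at 4.61, held 0.563 shared peaks per Mb, so near-equal backgrounds went with unlike densities. The rank relation does not give how much of the range in density background could account for. These were 2 relations, and the background is inferred from the called peaks themselves, each taken as a single position. No biological explanation was tested.

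For the called gene lists, long domains alone as the whole cause are argued against, because all 10 stayed called with 20 strata of length. Peak-rich chromosomes alone are argued against for 8 of the 10 lists, which stayed called with strata of chromosome and length. Those strata had only 3 length classes per chromosome. Finer length strata within chromosomes were not run, so both causes acting together are less well covered. A preference for genes used by every dividing cell could be tested on the ribosomal and cell cycle lists, which together had 3 of 52 genes bound against 2.60 expected, a ratio of 1.15 (exact 95% interval 0.24 to 3.19). The YAP/TEAD ratio of 4.67 had a lower limit of 3.48, above that interval. The intervals of all 9 other called lists overlapped it, so for them this comparison leaves the explanation open. Among them, the inflammatory list had a higher ratio than the YAP/TEAD list, 4.82, but a wider interval (2.68 to 7.13). The YAP/TEAD list was set apart after its values were seen. Overlap of intervals is not a test of a difference, and no such test was run. Open chromatin and the activity of these genes in 12Z cells were not analysed here and stay open.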
